A study of Arabidopsis thaliana with 2 samples.

How the data were processed

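The series compared anti-myc ChIP-seq libraries of etiolated seedlings, 1 from a PIF4-myc line and 1 from Col-0. Per the labels' protocols, seedlings were grown in darkness for 5 days, chromatin was sonicated, and libraries amplified over 18 PCR cycles were selected at about 300 bp including adapters and sequenced on an Illumina Genome Analyzer IIx. The growth label of the Col-0 library repeats the text on the transgenic line, so the groups were taken from the genotype label.

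The authors deposited 1 text file per library that lists aligned reads, with the chromosome, a position and the strand on each line and no header. Their values are positions, with other columns for chromosome and strand, and hold no count or scaled value as deposited. The submitters' processing notes name the TAIR 9 assembly, and the aligner and its filters are not given in the sources used here. The files themselves showed 2 properties that bear on the measurements. First, positions of the 2 strands were offset, with Col-0 plus and minus reads matching best at a lag of -40 bp. The lowest chloroplast positions were 20 on the plus strand and -17 (PIF4-myc) or -21 (Col-0) on the minus strand. Summits were placed in steps of 50 bp, and their accuracy was not tested. Second, the Col-0 file listed reads with several matches at each match and the PIF4-myc file did not. In the chloroplast inverted repeat, between 85000 and 110000, Col-0 had reads at 22507 plus positions, each of which (100%) had exactly the same number of lines at the mirrored position of the other copy, and PIF4-myc had 0 lines there. Bins of 1 kb with under 20% of the mean PIF4-myc reads held 29.2% of distinct Col-0 reads. The PIF4-myc share there, 0.782%, is low by the choice of bins, and no annotation of repeated sequence was used here.

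Of the nuclear lines, 16.1% in PIF4-myc and 34.3% in Col-0 repeated an earlier position and strand. At most 36 PIF4-myc lines shared a position, while 555 Col-0 positions had over 100 lines and together held 152593 lines, up to 4375 at 1 position. Reads were therefore counted once per position and strand. The chloroplast genome took 13.0% of PIF4-myc and 27.9% of Col-0 lines, the mitochondrial genome 1.30% and 5.86%, and both were left out.

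Regions were called on chromosomes 1 to 5. The lag with most pairs of plus and minus PIF4-myc reads was 59 bp as a running mean over 11 lags (57 bp without it), and each read was moved by 29 bp towards the fragment centre. The planned search range of 60 to 400 bp was moved to -10 to 330 bp for the strand offset and an assumed read length of 30 bp. Windows of 200 bp every 50 bp, 2382947 in all, were tested with an upper-tail Poisson test against the expected count, the depth ratio of 4.22 times the highest Col-0 rate over the surrounding 1, 5 and 10 kb and the genome. Windows with a Benjamini-Hochberg adjusted p under 0.01 and at least 2 times the expected count were merged within 100 bp, and the summit was the centre of the window with most PIF4-myc reads. Intervals of a ratio of 2 counts are exact (Clopper-Pearson) 95% intervals scaled by the depth ratio and cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The fold uses Col-0 rates over 1 kb or more and the ratio only the 2 counts of the window, so a fold can lie outside the interval. The procedure was tested on simulated reads at the depths of PIF4-myc against Col-0 with 200 planted sites. It recovered 1.49% of the 67 sites of 2 fold, 46.3% of the 67 sites of 4 fold and 98.5% of the 66 sites of 8 fold, with 1 region elsewhere, so regions of low fold are incompletely sampled. Both simulated libraries were Poisson draws from the same Col-0 rate smoothed over 10 kb, so they did not differ outside the planted sites. The 1 region elsewhere therefore gives no estimate of false regions in the real files, where the exchanged libraries gave 3548. Sites were planted only where the smoothed Col-0 rate lay in a middle range. The recovered shares therefore do not cover genes with raised Col-0 reads.

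Gene names came from a RefSeq gene table of assembly TAIR 10.1, which was used for names and for which genes lie next to a summit. To test whether the table could be laid over the files, PIF4-myc reads inside 625 nuclear tRNA genes were counted at 401 offsets. An offset of 0 bp gave the fewest reads, 72 against a median of 963, on all nuclear chromosomes together and was also the minimum on each of the 5. The table gives no strand, so transcription start sites, promoters, untranslated regions, exons and introns were not analysed here. In their place a gene counted as having a region when a summit lay inside its span or within 2 kb of it, summits were classed as inside a gene, within 1 kb of one or farther away, the nearest gene stood for the nearest start site, and the flank ratio used both 1 kb flanks with a pseudocount of 1 read. No genome sequence was used here, so the planned motif counts were not run. The class of regions of at least 8 fold was added after the data were examined.

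Gene lists, thresholds and the naming rule were fixed before the data were examined. Of 199 list loci, 198 were matched in the table and 1 was not analysed here. The tested lists held known PIF targets and shade markers, auxin, brassinosteroid, gibberellin, ethylene, light signalling, clock and flowering, chlorophyll and carotenoid, light harvesting and cell wall genes, and the comparison lists held housekeeping and seed storage genes. Each count of members with a region, and the median log2 flank ratio, was given as a percentile among 10000 random lists matched on 5 classes of gene length and 5 of Col-0 read density, or, for the alternative settings and gene families, on gene length and the distance to the neighbouring genes, with ties counted at their middle. Genes were named by rule: the nearest gene of the 10 regions with the smallest p, all PIF targets and shade markers, the 2 members of each other list with the highest region fold, and PIF4. PIN3, SAUR19, HBI1, BRI1, EXPA1, PHYA and the list members without a region were named after their values were seen. For a list member the values are those of its region with the highest fold, and for the alternative settings the fold is that of the window with the smallest p within 2 kb of the gene.

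Alternatives were all lines in place of distinct reads, adjusted p under 0.0001 or 0.05, 4 fold, a genome-wide background, an exact conditional binomial test of the 2 counts in a window, PIF4-myc reads thinned to the Col-0 number, scaling by 10 kb bins without a region, at least 25% of reads on each strand, a 200 bp fragment, 400 bp windows, the nearest gene or a 1 kb reach (for named genes added after the data were examined), and, added after the data were examined, scaling by the median ratio over 10 kb bins and removal of Col-0 reads in those low bins. The bins without a region were chosen for their lack of a PIF4-myc region, which by itself lowers the depth ratio found there. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.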

Results

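Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an anti-myc antibody on etiolated Arabidopsis thaliana seedlings, that is, seedlings kept in darkness, here for 5 days. The PIF4-myc group was a transgenic line that carried PIF4, a basic helix-loop-helix (bHLH) transcription factor that promotes hypocotyl elongation, fused to the myc epitope and driven by the PIF4 promoter. The Col-0 group was the wild type, which has no myc tag, and gave the background of the immunoprecipitation. Each group had 1 library, so no difference below has a replicate check, and intervals cover counting error only. The PIF4-myc library held 5480818 aligned lines, of which 4695324 lay on the nuclear chromosomes at 3937358 distinct positions and strands. The Col-0 library held 2145100 aligned lines, with 1420798 nuclear lines at 933642 distinct positions and strands. A window of 200 bp therefore held on average 6.61 distinct PIF4-myc reads and 1.57 distinct Col-0 reads, and the shallower Col-0 library limited the precision of every ratio. Positions are given on TAIR9.

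The question set by the design was where in the genome PIF4 was bound in dark-grown seedlings. PIF4-myc reads were concentrated in 20757 enriched regions, and the 10 regions with the smallest p lay next to genes of several kinds. The region next to XTH15, a xyloglucan endotransglucosylase of the cell wall, was at chromosome 4, 8139651 to 8140450, with its summit 1708 bp outside the gene, and held 335 PIF4-myc and 6 Col-0 reads at the summit, 44.1 fold over the expected count. The region nearest to ATHB2, a homeodomain-leucine zipper gene induced by shade, lay at chromosome 4, 9445601 to 9446300, with its summit 3114 bp from the gene, and reached 41.3 fold with 273 PIF4-myc and 3 Col-0 reads. A region at chromosome 2, 8138101 to 8139900, peaked 156 bp outside PHYB, which encodes a red and far-red light photoreceptor, at 27.0 fold with 319 PIF4-myc and 5 Col-0 reads.

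The highest fold, 54.2, was found 444 bp outside AT5G02580 at chromosome 5, 578551 to 580200, where 375 PIF4-myc reads stood against 3 Col-0 reads (exact 95% interval of the depth-scaled ratio 10.1 to 144). BBX29, a B-box zinc finger gene, had a region at chromosome 5, 22115301 to 22116300, that peaked 461 bp outside the gene at 45.4 fold. CKX5, a cytokinin oxidase gene, had one at chromosome 1, 28318251 to 28319300, that peaked 625 bp outside the gene at 28.7 fold. The region at chromosome 3, 22325351 to 22326600, lay between HAT3, a relative of ATHB2, and SHOT1, with its summit 3539 bp from HAT3 and 2848 bp from SHOT1, and reached 32.3 fold. The other regions of these 10 were nearest to AT1G69570 at 43.9 fold, to AT3G15220 at 41.0 fold and to AT5G57670 at 37.6 fold. The depth-scaled ratio at the last of these had a 95% interval of 5.68 to 29.6, below its fold. At the XTH15 region the interval was 6.02 to 36.3, also below its fold of 44.1.

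Over all regions the median fold was 3.93, with quartiles of 3.03 and 6.20. Of the 20757 regions, 3387 reached 8 fold, 726 reached 16 fold and 31 reached 32 fold. The regions had a median length of 400 bp, covered 7.84% of the nuclear genome, and held 35.6% of the distinct PIF4-myc reads and 9.25% of the distinct Col-0 reads. The same procedure with the libraries exchanged gave 3548 Col-0-enriched regions, of which 1989 held no PIF4-myc read at the summit and 1108 lay in annotated pseudogenes. The Poisson window test compares the reads of these 2 libraries, not the conditions. The count of regions moved with the settings, from 3282 with an exact binomial test of the 2 counts in each window, through 9427 with the PIF4-myc reads thinned to the Col-0 number and 10735 at 4 fold or more, to 63681 when depth was scaled on bins without a region.

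**Figure D1:**
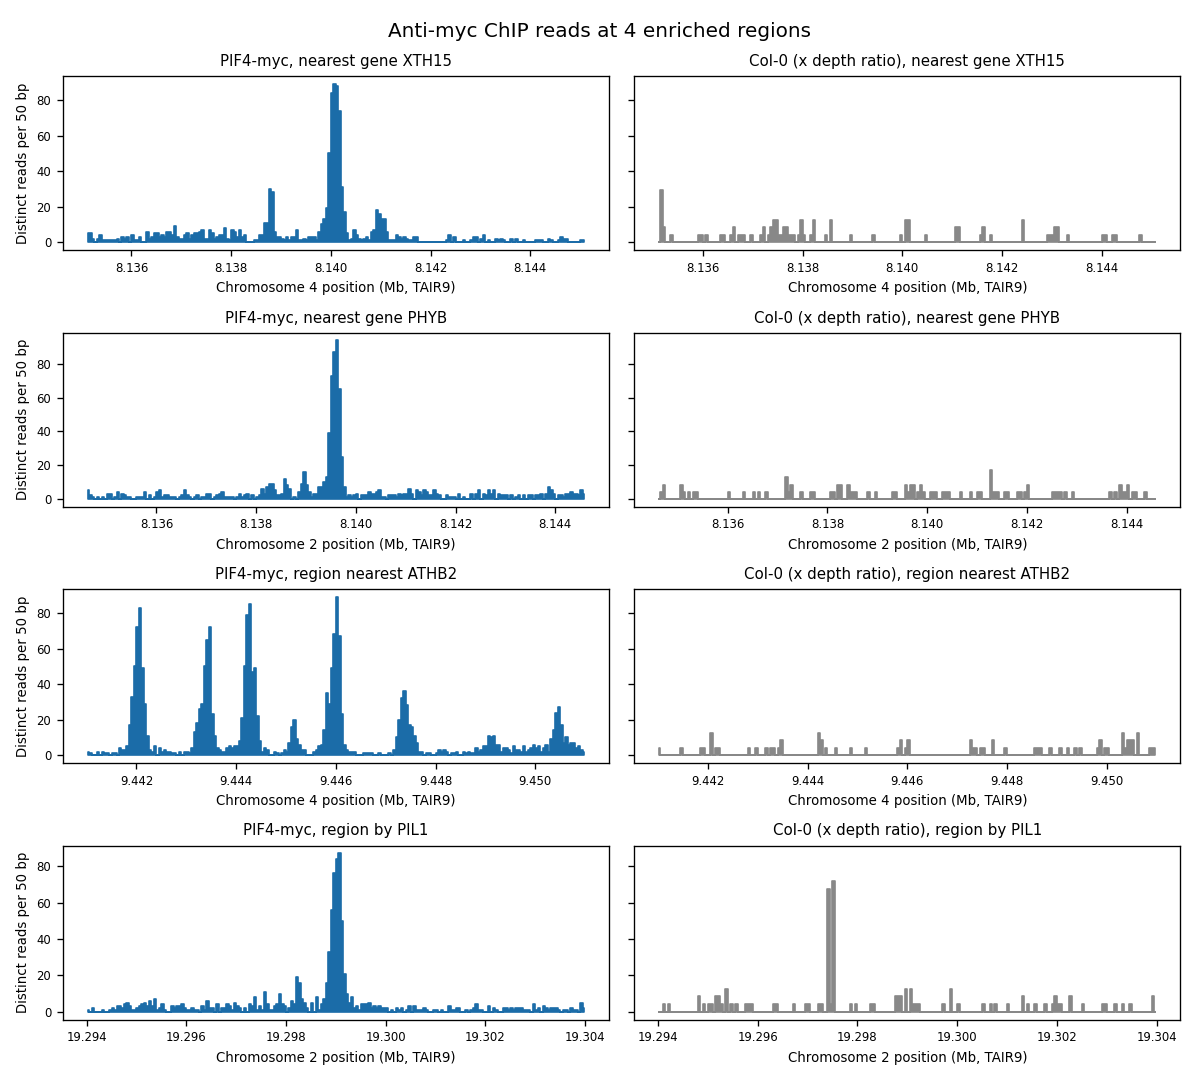
Distinct reads per 50 bp over 10 kb around the summits of 4 enriched regions, with chromosome position in Mb on the horizontal axis, for PIF4-myc (left) and for Col-0 multiplied by the depth ratio (right). At the summits the 200 bp windows held 335 PIF4-myc and 6 Col-0 reads near XTH15, 319 and 5 near PHYB, 273 and 3 near ATHB2, and 303 and 6 near PIL1, before scaling.

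Enriched summits lay next to genes more often than random positions did. Of all summits, 42.2% (Wilson 95% interval 41.5 to 42.8) were outside protein-coding genes but within 1 kb of one, against a mean of 20.3% for random positions on the same chromosomes and 18.2% for positions drawn from Col-0 reads. A further 41.8% (41.2 to 42.5) lay inside a gene, against 54.3% of random positions, and the other 3321 summits lay farther than 1 kb from any gene (interval of the share 15.5% to 16.5%), against 25.4% of random positions. Among the 726 regions of at least 16 fold, 48.1% (44.5 to 51.7) were within 1 kb of a gene, 20.4% (17.6 to 23.5) inside one and 31.5% (28.3 to 35.0) farther away. The PIF4-myc file lists no several-match reads, and neither kind of drawn position was limited to sequence where a PIF4-myc region could be called. How much of these differences follows from that was not tested. Summits outside genes had a median distance of 409 bp to the nearest gene end. When depth was scaled on bins without a region, the share within 1 kb of a gene was 23.6%.

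**Figure D2:**
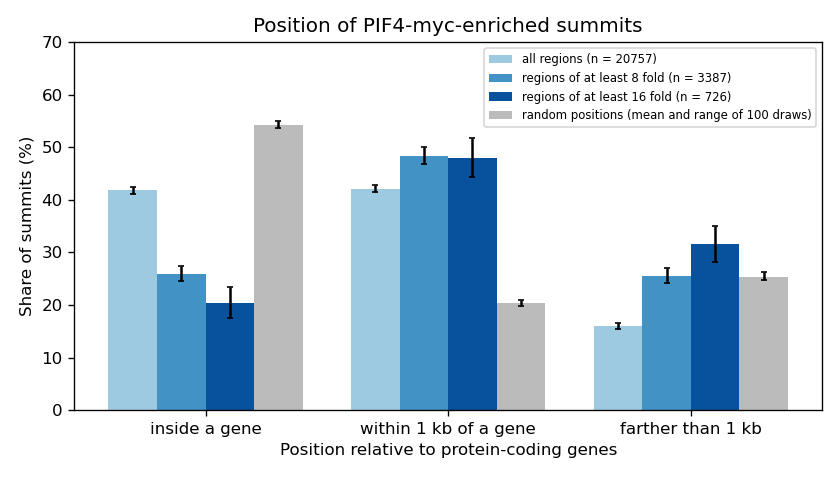
Share of enriched summits (vertical axis, %) inside protein-coding genes, within 1 kb of one and farther away, for all 20757 regions, the 3387 of at least 8 fold and the 726 of at least 16 fold, with Wilson 95% intervals, beside random positions (mean and range of 100 draws). The share within 1 kb of a gene was 42.2% for all regions and 20.3% for random positions, and the share inside genes was 20.4% for the regions of at least 16 fold.

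Of 27432 protein-coding genes, 19066 (69.5%) had an enriched summit inside the gene or within 2 kb of it, and 4543 (16.6%) had one of at least 8 fold. The gene lists fixed before the data were examined were therefore compared with 10000 random lists of the same size matched on gene length and Col-0 read density. Members of the 10 tested lists had a region in 165 of 172 cases, against a mean of 130.0 in random lists (percentile 100), and a region of at least 8 fold in 99, against 34.3 (percentile 100). With the main settings the 2 comparison lists lay inside the range of random lists. The exact binomial test gave 4295 genes with a region, a limit of 4 fold gave 11887 and the thinned reads gave 10997. When depth was scaled on bins without a region, 26403 genes had one, and 171 of the 172 members stood against 165.7 in random lists (percentile 99.3). The PIF targets, with 13 of 14 against 13.2, were then at percentile 37.0 and no single tested list was above 94.3. The bins used for that scaling were chosen for their lack of a PIF4-myc region, which lowers their ratio. With 26403 of the 27432 genes counted, random lists were near their ceiling and single lists had little room to exceed them. At 8 fold or more 163 of 172 stood against 129.2 with that scaling (percentile 100).

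With the main settings, genes known as PIF targets and shade markers had the highest share of members with a region of at least 8 fold among the tested lists. When depth was scaled on bins without a region, several lists had a higher share, such as gibberellin genes with 16 of 16 against 13 of 14. All 14 had a region, against 10.2 in random lists (percentile 99.4), and 13 had one of at least 8 fold, against 2.72 (percentile 100). PIL1, a bHLH gene induced by shade, had a region at chromosome 2, 19298701 to 19299350, with its summit 1142 bp outside the gene, 303 PIF4-myc and 6 Col-0 reads and 23.9 fold (95% interval of the depth-scaled ratio 5.44 to 32.9). HFR1, a bHLH gene that restrains PIF activity, reached 26.4 fold at chromosome 1, 468551 to 469900, with 245 PIF4-myc and 4 Col-0 reads. Among the homeodomain-leucine zipper genes, ATHB4 reached 30.2 fold, HAT1 28.0, HAT2 25.7 and HAT3 24.5, and ATHB2 had 4 regions within 2 kb with a highest fold of 17.2. YUC8, an auxin biosynthesis gene, reached 28.3 fold at chromosome 4, 14191751 to 14192750, and FHL, needed for nuclear import of phytochrome A, reached 22.7 fold 115 bp outside the gene. The depth-scaled ratios at FHL and HAT1 had 95% intervals of 3.16 to 12.5 and 3.82 to 20.1, below their folds. PAR1 and PAR2, which encode small growth-restraining bHLH-like proteins, reached 14.1 and 9.49 fold, IAA19 10.7 fold and IAA29 5.45 fold. A window within 2 kb of IAA29 held 84 PIF4-myc and 0 Col-0 reads (12.4 fold), at the edge of a region at chromosome 4, 15580451 to 15581450, that had its summit beyond 2 kb, reached 30.2 fold and is nearest to AT4G32272. With the exact binomial test IAA29 had no summit within 2 kb, and with depth scaled on bins without a region HAT2 had none. Regions called with that scaling overlapped 100% of the main regions, so the HAT2 region was still covered and only the summit lay elsewhere. Col-0 reads over the PAR1 gene were 9.55 times the genome mean, which raised the expected count at its region to 21.4 reads.

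Auxin and brassinosteroid genes also had regions more often than random lists. In the auxin list 33 of 34 members had a region (24.1 in random lists, percentile 100) and 26 had one of at least 8 fold (6.12, percentile 100). IAA2, an Aux/IAA repressor gene, had a region at chromosome 3, 8179951 to 8182350, with its summit inside the gene, 248 PIF4-myc and 2 Col-0 reads and 37.5 fold. PIN3, an auxin efflux carrier gene, had 165 PIF4-myc and 3 Col-0 reads at a summit inside the gene, and SAUR19 reached 21.5 fold at 495 bp. SAUR20 and SAUR21 shared a region, as did SAUR22 and SAUR23, and each of these genes was counted. IAA3 had no region, and Col-0 reads over that gene were 60.5 times the genome mean. In the brassinosteroid list 21 of 22 members had a region (17.0, percentile 98.7) and 16 had one of at least 8 fold (4.50, percentile 100). BEE3 and BEE1, bHLH genes induced by brassinosteroid, reached 25.6 and 20.9 fold, HBI1, a growth-promoting bHLH gene, 20.8 fold, and BRI1, the brassinosteroid receptor gene, 20.1 fold. BZR1, a transcription factor of the same pathway named in the study's title, was the member without a region, and Col-0 reads over it were 23.3 times the genome mean.

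Gibberellin, ethylene and cell wall genes had regions more often than random lists too. All 16 gibberellin genes had a region (12.4, percentile 99.2), 8 of them of at least 8 fold (3.65, percentile 99.0). That number was 5 with depth scaled by the median ratio (percentile 96.4) and also 5 without Col-0 reads in bins low in PIF4-myc reads (percentile 95.5). GA2OX6, a gibberellin-inactivating oxidase gene, reached 23.8 fold, and GAI, which encodes a DELLA growth repressor, reached 18.5 fold. All 13 ethylene genes analysed had a region (10.4, percentile 97.5), 9 of them of at least 8 fold (2.83, percentile 99.98). EIL1, a transcription factor of ethylene signalling, had a region at chromosome 2, 11548351 to 11549050, with 26.5 fold, and ACS8, an ethylene biosynthesis gene, had 23.7 fold. In the cell wall list all 16 members had a region (12.0, percentile 99.5) and 9 had one of at least 8 fold (3.01, percentile 99.96), led by XTH15, by EXPB1, an expansin gene, at 24.1 fold, and by EXPA1 at 22.3 fold.

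With the main settings, light signalling and clock genes had regions of at least 8 fold more often than random lists, while chlorophyll and light harvesting genes did not. In the light signalling list 20 of 22 members had a region (16.7, percentile 96.1) and 10 had one of at least 8 fold (4.51, percentile 99.6). After PHYB, FHL and PHYA, at 22.4 fold, had the highest folds of that list, and PHYC and HYH had no region. All 15 clock and flowering genes had a region (11.4, percentile 99.2), 9 of them of at least 8 fold (2.82, percentile 99.99), with GI at 18.3 fold and PRR9 with 106 PIF4-myc and 3 Col-0 reads at its summit. The median log2 ratio over the 1 kb flanks of the clock genes, 0.83, stood at percentile 81.2 of random lists. With depth scaled by the median ratio, the members with a region of at least 8 fold fell to 4 of 15 for the clock genes (percentile 94.8) and to 6 of 22 for light signalling (percentile 96.9). Without Col-0 reads in bins low in PIF4-myc reads they also numbered 4 (percentile 94.5) and 6 (percentile 96.7). With depth scaled on bins without a region light signalling had 20 of 22, against 17.5 (percentile 90.9). All 13 chlorophyll and carotenoid genes had a region (10.1, percentile 98.0), but only 2 had one of at least 8 fold (2.58, percentile 36.8; with depth scaled on bins without a region, 13 against 10.6, percentile 96.7). These were PORB, a protochlorophyllide oxidoreductase gene, at 19.6 fold and PSY, the phytoene synthase gene of carotenoid synthesis, at 12.4 fold. PORB had no region when each summit was given to its nearest gene only, and PSY had none within 1 kb. Of the 12 light harvesting complex genes, 9 had a region (8.99, percentile 48.4) and 1, LHCA2 at 22.3 fold, reached 8 fold (2.33, percentile 18.1; with that scaling 9 against 8.42, percentile 62.4). The LHCA2 summit held 256 PIF4-myc and 9 Col-0 reads. The 95% interval of its depth-scaled ratio ran from under 8 to 14.9, below its fold. LHCA4 had 6.66 fold, and its region was lost with the exact binomial test.

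Among the comparison lists, 13 of 15 housekeeping genes had a region (11.9, percentile 73.9) and 2 had one of at least 8 fold (3.55, percentile 18.5), ACT2 at 11.7 fold and UBC9 at 9.54 fold. With thinned reads 10 of the 15 had a region, against 6.41 in lists matched on gene length and gene spacing (percentile 96.8). At 8 fold or more 3 had one with those reads (2.91, percentile 54.45). Of 11 seed storage and oil body genes, 7 had a region (7.22, percentile 43.5) and 3 had one of at least 8 fold (1.73, percentile 83.8), with CRB at 13.0 fold and CRC at 11.1 fold. Neither was the nearest gene of a summit. With the exact binomial test 91 of the 172 tested members had a region, against 31.0 in lists matched on gene length and gene spacing (percentile 100). That test left a region at 6 of 16 gibberellin genes (3.11 in such lists, percentile 95.4), 11 of 22 light signalling genes (4.03, percentile 99.97), 6 of 15 clock genes (2.55, percentile 98.3) and 7 of 16 cell wall genes (2.88, percentile 99.1). It left one at 3 of 13 chlorophyll genes (1.92, percentile 79.5) and at 1 of 12 light harvesting genes (1.86, percentile 27.7). Of the comparison lists, seed storage genes had a region in 3 of 11 cases (1.58, percentile 87.0) and housekeeping genes in 0 of 15 (2.42, percentile 3.28), with ACT2 and UBC9 among those lost.

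**Figure D3:**
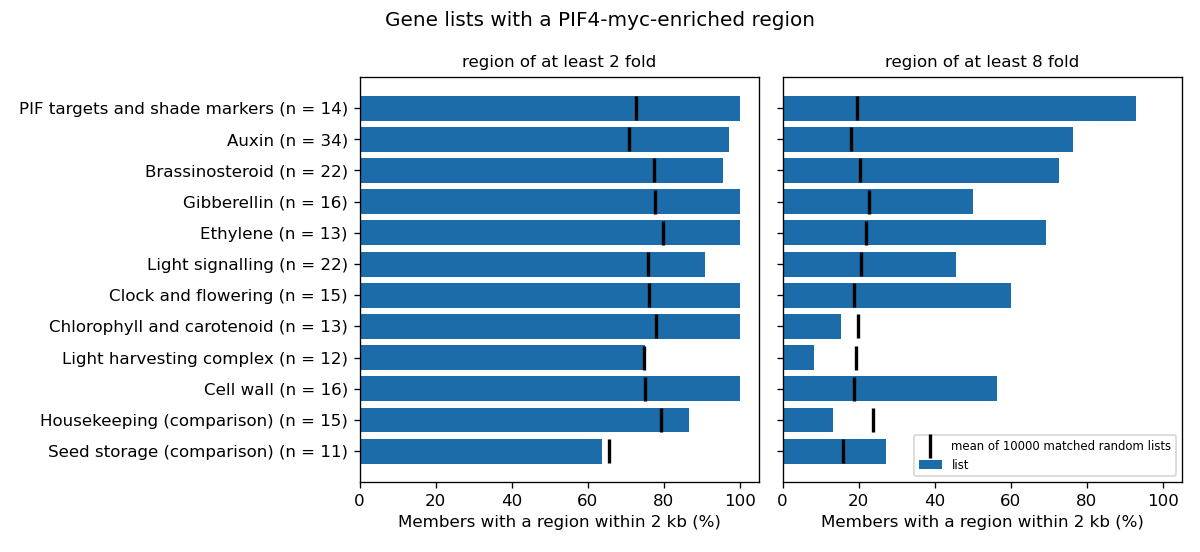
Share of the members of each gene list (horizontal axis, %) with an enriched summit in the gene or within 2 kb, at 2 fold or more (left) and 8 fold or more (right). Bars stand for the lists and black marks for the mean of 10000 random lists matched on gene length and Col-0 read density. At 8 fold or more, 13 of 14 PIF targets and shade markers and 1 of 12 light harvesting genes had a region.

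PIF4 itself, a copy of which the transgene also carries, had a region at chromosome 2, 17885451 to 17886550, with its summit 401 bp outside the annotated gene. The summit window held 224 PIF4-myc and 2 Col-0 reads, a depth-scaled ratio with a 95% interval of 7.27 to 221. The fold over the expected count was 6.04, because Col-0 reads over the neighbouring PIF4 gene were 13.5 times the genome mean and raised the expected count to 37.1 reads. From 17887001 to 17889000, inside the gene, 714 PIF4-myc and 312 Col-0 reads were counted. No enriched summit lay inside the gene, although the region reached into it. Between 17887001 and 17889000 a call was hardly possible, because the Col-0 reads raised the expected count. Other stretches that overlap the gene held 376 PIF4-myc and 7 Col-0 reads (17886001 to 17886500) and 75 and 1 (17889001 to 17889500). Reads of the transgene and of the endogenous locus cannot be separated in these files.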

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

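The scalings by the median ratio and without Col-0 reads in bins low in PIF4-myc reads were chosen after the data were examined, and all other settings before. No paired analysis was possible because each group had 1 library, and no replicate could be left out. The 20757 enriched regions became 10735 at 4 fold or more, 3282 with the exact binomial test, 9427 with thinned PIF4-myc reads and 63681 with scaling by bins without a region. The 3548 Col-0-enriched regions became 1968 at adjusted p under 0.0001, 6665 with the binomial test, 787 with scaling by bins without a region and 1953 without those bins. The 19066 genes with a region became 11887 at 4 fold, 4295 with the binomial test and 10997 with thinned reads, and the 165 list members became 91 with the binomial test. The share of summits within 1 kb of a gene, 42.2%, was 37.4% with all lines, 45.1% at adjusted p under 0.0001, 39.7% at 0.05, 46.6% at 4 fold, 39.7% with a genome-wide background, 47.4% with the binomial test, 45.9% with thinned reads, 23.6% with scaling by bins without a region, 40.3% with 400 bp windows, 44.8% with the median ratio and 44.3% without the low bins. Thinning removes PIF4-myc reads by construction, and the cause of the other changes was not tested. The depth ratio was 4.22, against 1.20 over the 3592 bins without a region, 5.42 by the median and 5.91 without the low bins. The value of 1.20 is low in part by the choice of bins that lack a PIF4-myc region. How far reads listed at several matches in the Col-0 file alone lowered it was not tested. Of the 41 named genes, IAA29, LHCA4, ACT2 and UBC9 had no summit within 2 kb with the binomial test and HAT2 had none with scaling by bins without a region. By the nearest gene PORB, CRB and CRC lost theirs, and at a 1 kb reach PSY and CRB did, both looked at after the data were examined. The thinned reads gave regions at 42.9% of the 20757 by 1 bp or more and at 35.1% by 50% of both. With scaling by bins without a region, the PIF target list went from above the mean of random lists to below it (13 against 13.2). Both values were near the ceiling of 14. The regions of that setting overlapped 100% of the 20757, so the HAT2 region was still covered and only the summit lay elsewhere. The motif settings were not run because no genome was used here, and the depth of Col-0, 1.57 distinct reads per 200 bp, limits the folds.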

Other observations

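The gene families below, the comparison of tRNA gene flanks between the libraries, the count of studied genes among the densest Col-0 genes and the count of empty steps over PIF4 were chosen after the data were examined. SAUR genes, a family of small auxin-induced proteins, had a region within 2 kb in 71 of 80 cases, against 42.2 in random lists matched on gene length and gene spacing, and one of at least 8 fold in 38, against 10.5. A region counts for every gene within 2 kb, so neighbouring SAUR genes can share one, as SAUR20 and SAUR21 did. The random lists drew genes singly, so these members are not independent and the contrast may be overstated. Of 32 genes with an Aux/IAA number as symbol or synonym, 30 had a region (21.4 in random lists), 18 of them of at least 8 fold (6.12). All families were taken by symbol or synonym without a further check, so a family can hold genes of another kind. Of 54 homeobox genes of the HB and HAT kind, 48 had a region (36.0), 26 of them of at least 8 fold (10.6), and of 30 B-box genes 28 had one (21.1), 13 of them of at least 8 fold (4.96). At 8 fold or more these 4 families stayed at percentile 98.1 or higher in each of the 6 other settings tried. For any region, scaling by bins without a region put B-box genes at percentile 46.7, HB and HAT genes at 83.4 and Aux/IAA genes at 91.7. Of 71 WRKY genes, 58 had a region (49.3 in random lists, percentile 99.0, but 28.6 with the exact binomial test and 86.0 with scaling by bins without a region), 13 of them of at least 8 fold (13.9, percentile 40.8). Of 54 ribosomal protein genes, 39 had a region (38.3, percentile 57.9), and 3 had one of at least 8 fold (7.42, percentile 3.11), but at 8 fold they stood at percentile 18.3 with thinned reads and 40.1 with scaling by bins without a region.

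Of the 16 families tried, ERF genes had a region in 23 of 25 cases (14.2 in random lists, percentile 99.99, but 88.2 with the exact binomial test), 7 of them of at least 8 fold (3.97, percentile 94.0). The others lay nearer to random lists for any region: 17 of 25 auxin response factor genes of the ARF kind (18.5, percentile 24.3), 14 of 23 alpha expansin genes (15.5, percentile 24.97), 24 of 33 XTH genes (22.3, percentile 73.0), 7 of 8 PIN genes (5.98, percentile 77.2) and 25 of 35 response regulator genes (24.99, percentile 49.1) had one. At 8 fold or more these were at percentiles 85.9, 97.5, 94.96, 94.6 and 95.8. Other settings moved some of them for any region. XTH genes were at percentile 99.4 at a limit of 4 fold and 98.8 with thinned reads, and ARF genes at 0.035 with scaling by bins without a region. NAC (72 of 99), MYB (87 of 125), CKX (5 of 7) and defensin-like genes (55 of 111) were at percentiles 74.0, 78.1, 42.6 and 24.96 for any region, and 95.2, 76.6, 68.1 and 69.0 at 8 fold or more.

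Some genes were the nearest gene of many separate regions. GATL3, ABCB19, which encodes an auxin transporter, and BXL1 were each the nearest gene of 10 regions, and NCED3, an abscisic acid biosynthesis gene, of 9. HA2, a plasma membrane proton pump gene, had 8 regions, the auxin carrier gene AUX1 and the auxin receptor gene AFB2 had 7 each, and PIN7 had 6. In all, 245 genes had at least 5 regions, out of 13363 that were the nearest gene of any region.

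PIF4-myc reads rose next to nuclear tRNA genes, which are transcribed by RNA polymerase III. An enriched summit lay within 200 bp of 31.8% of the 625 tRNA genes. That was above the highest of 1000 draws from the gaps between protein-coding genes (mean 9.52%, highest 13.6%). The draws were not matched to tRNA genes on distance to a protein-coding gene or on repeated sequence. Regions of neighbouring genes therefore cannot be set aside as a part of the difference. Reads 50 to 150 bp outside tRNA genes exceeded those 1000 to 2000 bp outside by 2.24 times in PIF4-myc and 1.22 times in Col-0, a ratio of 1.84 (95% bootstrap interval over tRNA genes 1.46 to 2.31). The rise thus differed between the libraries. Only the Col-0 file lists several-match reads, so the values cannot decide whether both libraries recovered this chromatin alike. The enrichment was weak, with a summit of at least 8 fold near 0.48% of tRNA genes against 2.07% of random positions. Binding of PIF4 there may be put forward as a hypothesis, while a difference in shearing or recovery between the libraries was not tested and stays open.

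Reads were dense over parts of PIF4 and other studied genes in both libraries. For this count, short genes and genes with a stretch low in PIF4-myc reads were left out, which kept 15698 protein-coding genes. Of the 20 of these with most Col-0 reads per kb, 6 belong to the tested lists, against a mean of 0.169 and a highest value of 3 in random draws from the same genes. They were IAA3 at 60.5 times the genome mean, BZR1 at 23.3, PIF4 at 13.5, RGA at 9.84, PAR1 at 9.55 and PRE1 at 8.46. Even cover of the gene in Col-0 is argued against by 12 of 40 steps of 50 bp with no Col-0 read over PIF4 from 17887001 to 17889000, where an even spread of the 312 reads left at most 1. PIF4-myc reads were also fewer in those empty steps, with a mean of 5.83 against 23 in the other steps. Accessible chromatin need not give even cover, so this count cannot decide on it. Cloned coding sequence of genes in use in the laboratory may have entered both libraries, a hypothesis found and tested on the same data. Extra PIF4 copies in the transgenic line (lower quartile of window ratios over the gene 0.545) and an enriched summit inside the gene (0 found) stay open. Between 17887001 and 17889000 the raised Col-0 reads lower the depth-scaled ratios, to 0.504 to 0.606, and raise the expected count. In the other stretches that overlap the gene the ratios were 11.3, 6.34 and 9.39.

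Members of the tested lists had regions more often than random lists. Longer gaps between these genes and their neighbours do not account for it, since the pooled count of 165 stood at percentile 100 of lists matched on gene length and gaps (mean 121.5). The count did not rest on the SAUR, LHCB1 and LHCB2 genes, which have near-identical copies. Against lists matched on gene length and Col-0 read density, 157 of the 161 other members had a region, at percentile 100 (mean 122.9). The PIF4-myc file lists no several-match reads, so this says little on shared reads as a cause. The preference for these genes may be biological, as a hypothesis. Open chromatin at genes active in dark-grown seedlings was not tested as an explanation, and the lists hold genes chosen for their known part in growth and light responses.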
